A study of Homo sapiens with 6 samples.

How the data were processed

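Human pancreatic islets from 1 donor were cultured overnight at 5 mM glucose in wells of 300 islets and treated in duplicate, per the labels' protocols, and RNA was measured by sequencing. The 6 libraries fall into 3 groups of 2. Control wells received 0.1% DMSO for 2 h. A second group received interleukin-1beta (IL-1beta) at 50 ng/mL with 11 mM glucose for 2 h. The last group received 1 uM FK506, an inhibitor of the phosphatase calcineurin, for 30 min and then the same IL-1beta and glucose. IL-1beta and high glucose were always given together, FK506 was never given without them in the libraries used, and the FK506 wells were treated for 30 min longer. A change named after IL-1beta below is one with both, and their parts cannot be told apart. The glucose level of the control wells during those 2 h is not given in the sources used here. Whether the IL-1beta wells without FK506 received DMSO is not given in the sources used here.

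The data are 3 tables of the authors' own comparisons over the same 18506 genes. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the genome build GRCh38, and the versions are not given in the sources used here. Per the file headers, each table holds the overall mean and the group means of normalized counts, the log2 fold change, its standard error (SE), the test statistic as a score and the p-value and adjusted p-value. The normalized count of a group in the deposited tables is a signal averaged over libraries, so it has no spread or n of its own here. Values of single libraries were not used here. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

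The tables were checked for what they hold. The fold change of FK506 plus IL-1beta against control differed from the sum of the other 2 log2 fold changes by at most 4.9e-08. The log2 fold changes lay within 0.041 of the log2 ratio of the group means, so they were not shrunken. The adjusted p-values were Benjamini-Hochberg values of the deposited p-values. In the comparison of FK506 plus IL-1beta with IL-1beta, 10046 genes with an overall mean of up to 294.1 have no adjusted p, and 8460 genes from 294.4 upward have one; a missing adjusted p was kept as missing. The overall mean lay outside the range of the 3 group means in 3596 genes (19.4%), so the authors' fit held further libraries, which were not analysed here.

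A gene was called at an adjusted p under 0.05 in the authors' deposited table. The 28 gene lists (631 entries) and the rule for named genes were fixed before the data were examined. In each comparison the rule takes, among genes with a symbol and an overall mean of at least 50, the 10 largest called changes in each direction, then up to 4 called members per list with the largest test statistic, and always NFKBIA, CXCL8, RCAN1, NR4A1, TNF, IL6, INS and GCG. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen. Genes were placed on GRCh38 with GENCODE release 29, which holds 18444 of the genes; the 62 others have no symbol in the tables. Of the list symbols, 3 were matched through a table of gene names.

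Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited test statistic, against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation needs values of single libraries, so no list call could be checked with one. For lists whose members move together, the preset value makes the p-values too small. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. The share of the response kept with FK506 was the slope through the origin of the log2 fold change with FK506 on that without it, over the genes called without it. For genes whose control mean is 0, a fold is given against a floor of 3 counts over the control group, and for those with up to 3 control counts as a ratio with an exact 95% interval, both from normalized counts and for counting error only.

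Alternatives were other thresholds, filters on the overall mean, no independent filtering, recentring on the median, a t reference with 2 degrees of freedom, and other settings of the list test. Removal of the trend of log2 fold change on GC content and transcript length (local regression over 0.3 of the genes, with values for 99.7% of genes) and lists without shared genes were added after seeing the data. The steps were tested on simulated data, in which the planted trend and groups of shifted genes were also recovered. For IL-1beta against control, 200 genes with an overall mean of at least 50 were changed among the 18506 genes. Changes of 0.5 on the log2 scale were recovered in 51.0% and changes of 1.0 in 92.0%. Genes with an overall mean under 50 were not tried. Among the 8460 genes with an adjusted p in FK506 plus IL-1beta against IL-1beta, 89.0% of changes of 0.5 were recovered.

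Depth sets part of the precision. The library totals are unknown here. The group means sum to 16094280 normalized counts in control, 17747665 with IL-1beta and 17415946 with FK506 plus IL-1beta. Normalization takes out differences in depth, so these sums do not show which group was sequenced more deeply. In IL-1beta against control the median SE of the log2 fold change was 0.50 for genes with an overall mean under 50, 0.19 from 50 to 500 and 0.09 from 500 upward. The replicates of the 3 groups are wells of islets from 1 donor, so the p-values say nothing of other donors. They rest on the spread between the libraries of the authors' fit, which held further libraries.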

Results

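Islets, the endocrine cell clusters of the pancreas, were profiled by RNA sequencing after 2 h of IL-1beta with 11 mM glucose, with or without FK506, and after DMSO. There were 2 libraries in each of the 3 groups, and the study asked which genes islets express under combined inflammatory and metabolic stress and what calcineurin and the transcription factor NFAT contribute. All fold changes, SEs and adjusted p-values are the authors' DESeq2 values, written as log2 fold change ± SE.

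IL-1beta with high glucose raised inflammatory genes strongly within 2 h. In the authors' deposited table, 3651 of 18506 genes changed, 2346 of them higher and 1305 lower. Of these, 820 rose at least 2-fold against 134 that fell at least 2-fold. The neutrophil-attracting chemokine CXCL3 rose by 7.77 ± 0.40, the T-cell and dendritic-cell attractant CCL20 by 7.52 ± 0.41 and CXCL1 by 6.55 ± 0.24 in the authors' deposited table. In the same comparison of the authors' deposited table, the endothelial adhesion gene SELE rose by 6.89 ± 0.19 and IL1B, the gene of IL-1beta itself, by 7.56 ± 0.60. The genes of the colony-stimulating factors CSF3 (chromosome 17, 40015361 to 40017813) and CSF2 were listed at 0 in control, and the means of the authors' deposited table put them at least 151-fold and at least 95-fold higher, respectively. The long noncoding RNA LINC02605 rose by 7.74 ± 0.21 and VNN3 by 6.93 ± 0.66 in the authors' deposited table. The uncertain transcript AL136531.3 was 123 times its control level (counting interval 41.9 to 601) by the means of the authors' deposited table.

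Genes of the NF-kB pathway, the main transcriptional route of IL-1 signalling, rose almost as a group. In the authors' deposited table, 24 of 25 measured feedback and pathway genes rose (25 when adjusted over the list alone), and the list was higher than other genes at an adjusted p of 4.57e-167. The inhibitor NFKBIA (chromosome 14, 35401511 to 35404749) rose by 4.53 ± 0.14 in the authors' deposited table, the apoptosis inhibitor BIRC3 by 5.07 ± 0.09, the ribonuclease ZC3H12A by 5.07 ± 0.12 and NFKB2 by 3.74 ± 0.09. Of 28 other NF-kB effector genes 26 rose (26 adjusted over the list alone, list adjusted p 2.02e-127), with the leukocyte adhesion gene ICAM1 at 5.35 ± 0.08 and the mitochondrial superoxide dismutase SOD2 at 4.09 ± 0.07 in the authors' deposited table. Chemokine genes rose in 15 of 18 (15 adjusted over the list alone, list adjusted p 1.66e-46), including CXCL8 at 6.33 ± 0.22, CXCL2 at 6.11 ± 0.15 and CX3CL1 at 4.53 ± 0.21 in the authors' deposited table. Cytokine genes rose in 19 of 20 (19 adjusted over the list alone, list adjusted p 1.37e-21), with IL6 at 3.06 ± 0.27, LIF at 3.25 ± 0.12 and CSF1 at 4.03 ± 0.24 in the authors' deposited table. TNF had 41.7 times its control level (counting interval 13.9 to 205) by the means of the authors' deposited table.

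Early response genes rose as well. Of 31 immediate-early genes 24 rose in the authors' deposited table (24 higher and 1 lower adjusted over the list alone, list adjusted p 1.17e-37), with BTG2 and MAFF both at 2.59 and JUNB at 2.06 ± 0.08. Phosphatase and Sprouty feedback genes of MAP kinase signalling rose in 8 of 13 and fell in 1 (8 and 2 adjusted over the list alone, list adjusted p 3.28e-06), with DUSP5 at 1.55 ± 0.11 in the authors' deposited table. Interferon-stimulated genes rose in 16 of 30 and fell in 1 (17 and 1 adjusted over the list alone, list adjusted p 4.92e-06), with the GTPase GBP1 at 2.77 ± 0.16 and the RNA sensor IFIH1 at 1.21 ± 0.10 in the authors' deposited table. Apoptosis regulators rose in 11 of 24 and fell in 2 (12 and 2 adjusted over the list alone, list adjusted p 2.02e-10), both the death-promoting BBC3 at 3.72 ± 0.23 and the protective CFLAR at 1.28 ± 0.06 and MCL1 at 1.22 ± 0.07 in the authors' deposited table. Reported NFAT target genes rose in 11 of 19 and fell in 2 (12 and 2 adjusted over the list alone, list adjusted p 2.30e-10), among them CXCL8, CCL2 at 4.09 ± 0.23 and EGR3 at 2.29 ± 0.14 in the authors' deposited table. All 19 measured members of that list are also in another list. Target genes of CREB and its coactivators CRTC rose in 13 of 21 and fell in 1 (14 and 2 adjusted over the list alone, list adjusted p 2.24e-05), with NR4A3 at 1.31 ± 0.13, NR4A2 at 1.27 ± 0.12 and CREM at 1.16 ± 0.11 in the authors' deposited table. RCAN1, a calcineurin regulator and NFAT target, rose by 0.52 ± 0.14 and NR4A1 by 1.15 ± 0.18 in the authors' deposited table.

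Islet identity genes fell, while the insulin and glucagon genes did not pass the test. In the authors' deposited table, 15 of 29 beta cell genes fell and 3 rose (15 and 3 adjusted over the list alone, list adjusted p 2.93e-05). The beta cell transcription factor gene NKX6-1 (chromosome 4, 84491987 to 84498450) fell by 1.30 with an SE of 0.08 in the authors' deposited table. The neuropeptide gene ADCYAP1 rose by 1.65 ± 0.07 and the signalling regulator RGS16 by 1.44 ± 0.09 in the authors' deposited table. Alpha cell genes fell in 8 of 16 (9 adjusted over the list alone, list adjusted p 1.17e-05), among them KCTD12 at -0.82 ± 0.08 in the authors' deposited table. INS, the insulin gene, was at 0.20 ± 0.18 with an adjusted p of 0.531 in the authors' deposited table. GCG, the glucagon gene, was at -0.11 ± 0.13 with an adjusted p of 0.654 in the authors' deposited table. Among the largest falls called at an overall mean of at least 50 were FLRT2 at -1.83 ± 0.35, PRLHR at -1.83 ± 0.34, PRR15L at -1.56 ± 0.32 and the potassium channel gene KCNJ3 at -1.52 ± 0.19 in the authors' deposited table. INS-IGF2, at -1.50 ± 0.18 in the authors' deposited table, spans the INS gene, so its count is uncertain. Endothelial genes fell in 6 of 15 and rose in 1 (7 and 2 adjusted over the list alone, list adjusted p 0.0267), with the VEGF receptor gene KDR at -0.90 ± 0.10 in the authors' deposited table. None of 27 acinar genes was called in the authors' deposited table, where their list had an adjusted p of 0.853, and ductal genes rose in 2 and fell in 4 of 21 (list adjusted p 0.792).

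Most other lists did not pass the test. Unfolded protein and integrated stress response genes rose in 8 of 25 and fell in 1 (8 and 2 adjusted over the list alone, list adjusted p 0.0249), with ATF3 at 2.48 ± 0.17 and PPP1R15A at 1.85 ± 0.16 in the authors' deposited table. Ribosomal protein genes rose in 4 of 44 (0 adjusted over the list alone), and their list adjusted p was 0.0338. Calcineurin-NFAT pathway components rose in 10 of 24 (list adjusted p 0.315), with NFATC2 at 0.65 ± 0.13 in the authors' deposited table. Glucose-regulated genes went both ways, 6 higher and 7 lower of 19 (list adjusted p 0.988), with KLF10 at 0.77 ± 0.07 and ARRDC4 at -0.82 ± 0.09 in the authors' deposited table. Mitochondrially encoded genes rose in 9 of 15 (13 adjusted over the list alone, list adjusted p 0.0565) and heat shock genes in 5 of 15 (7 adjusted over the list alone, list adjusted p 0.179). With ranks both lists tested higher, at adjusted p-values of 2.43e-05 and 0.0167. Delta and PP cell genes rose in 2 and fell in 5 of 12 (list adjusted p 0.621). The lists of stellate, macrophage, lymphocyte and mast cell, metallothionein, hypoxia and cell cycle genes had adjusted p-values from 0.465 to 0.988, with at most 3 called members each. The acinar, ductal, stellate, macrophage and lymphocyte and mast cell lists had medians above 0 while their test pointed lower, none past the threshold. A t reference of 2 degrees of freedom, fewer than the authors' fit leaves, was too strict to decide. With it 0 genes passed, against 1650 at an unadjusted p under 0.05. The calls of the endothelial, unfolded protein and ribosomal protein lists ended with a preset correlation of 0.05, at adjusted p-values of 0.0921, 0.116 and 0.1945, and that of the ribosomal protein list also with the GC and length trend removed, at 0.185, and with an overall mean of at least 100, at 0.172. The unfolded protein call also ended with ranks (0.102), with an overall mean of at least 100 (0.0678) and without shared genes (0.218).

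**Figure D1:**
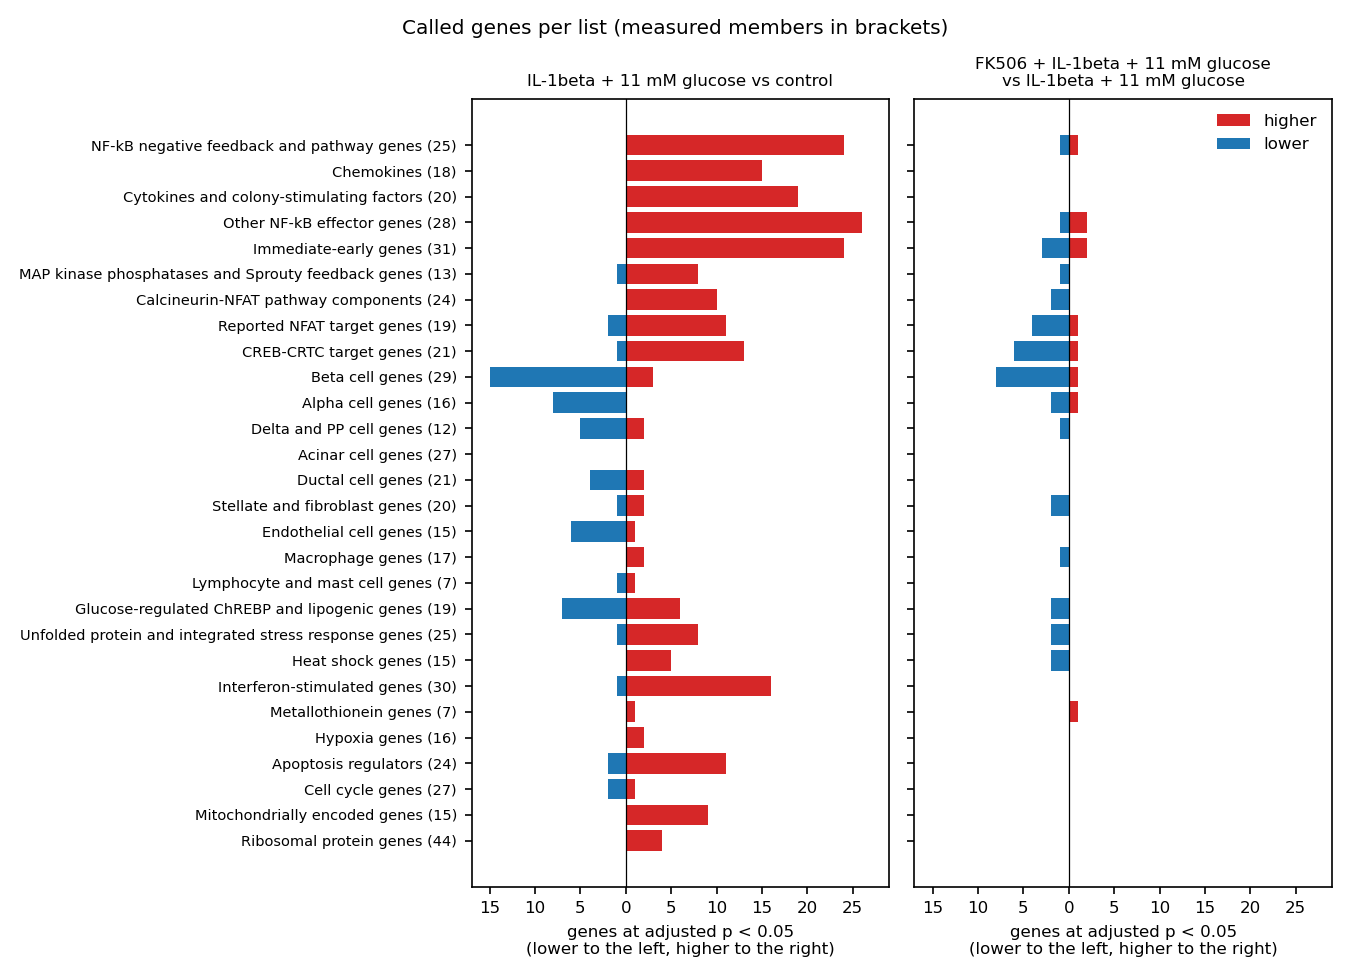
Number of genes at an adjusted p under 0.05 per list (x axis, lower to the left and higher to the right), for IL-1beta with 11 mM glucose against control and for FK506 added to it; brackets give the measured members. NF-kB pathway genes rose in 24 of 25 with IL-1beta, while FK506 moved 1 up and 1 down, and beta cell genes fell in 15 of 29 and 8 of 29.

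FK506 given before IL-1beta changed few genes, most of them downward and by little. In the authors' deposited table, 312 of 8460 genes with an adjusted p changed, 259 lower and 53 higher, and 5 fell and 1 rose at least 2-fold. The orphan nuclear receptor gene NR4A2 (chromosome 2, 156324432 to 156342348) was at -1.85 ± 0.13 in the authors' deposited table (adjusted p 1.72e-40). The gluconeogenic gene PCK1 was at -1.35 ± 0.18 in the authors' deposited table, the pyruvate dehydrogenase kinase gene PDK4 at -1.25 ± 0.14 and the insulin receptor substrate gene IRS2 at -1.04 ± 0.09. NR4A3 at -0.96 ± 0.13, the cAMP-response factor gene CREM at -0.90 ± 0.11, CITED2 at -0.83 ± 0.08, RGS16 at -0.82 ± 0.08 and the prostaglandin synthase gene PTGS2 at -0.72 ± 0.15 were lower too in the authors' deposited table. Among the largest called rises were the zinc finger factor gene EGR3 (chromosome 8, 22687659 to 22693302) at 1.26 ± 0.11, TNFAIP2 at 0.64 ± 0.16, CAMKK1 at 0.61 ± 0.09, HIVEP3 at 0.60 ± 0.08, BDKRB2 at 0.58 ± 0.09 and EGR1 at 0.54 ± 0.14 in the authors' deposited table. A gene without a symbol, ENSG00000223414, was at -1.24 ± 0.09 in the authors' deposited table and was chosen after its values were seen.

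Few inflammatory genes passed the test for a change with FK506. Of 25 NF-kB pathway genes 1 rose and 1 fell in the authors' deposited table (3 and 3 adjusted over the list alone, list adjusted p 0.502), namely TRAF1 at 0.53 ± 0.12 and ZC3H12C at -0.23 ± 0.07. The latter was at -0.13 with an adjusted p of 0.535 once the GC and length trend was removed. Of 28 other NF-kB effector genes 2 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p 0.323), and of 31 immediate-early genes 2 rose and 3 fell (3 and 4 adjusted over the list alone, list adjusted p 0.376). The immediate-early list tested higher with ranks of the statistic, at an adjusted p of 0.00549, and without shared genes, at 0.000508. NFKBIA at 0.14 ± 0.14, CXCL8 at -0.04 ± 0.22 and IL6 at 0.16 ± 0.24 did not pass the test, and TNF at 0.34 ± 0.32 had no adjusted p in the authors' deposited table. No chemokine or cytokine gene was called in the authors' deposited table, where 10 of 18 and 12 of 20 had no adjusted p (0 and 2 higher adjusted over the list alone). Their lists nevertheless lay above other genes, with a median of 0.24 and an adjusted p of 0.00435 for chemokines and a median of 0.34 and an adjusted p of 0.000259 for cytokines.

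Some target genes of CREB and CRTC were among the genes lower with FK506. In the authors' deposited table, 6 of 21 fell and 1 rose (8 and 2 adjusted over the list alone, list adjusted p 4.62e-18), among them NR4A2, IRS2, NR4A3 and CREM. Ranks of the statistic ended that call at an adjusted p of 0.0637. The median of the 21 was -0.19, with 13 below 0 and 8 above. A split chosen after the results were seen left out CREM, NPAS4 and the 4 genes shared with the NFAT list. The other 15 had a median of 0.02 (list test p 0.596). Reported NFAT target genes fell in 4 of 19 and rose in 1 in the authors' deposited table (4 and 1 adjusted over the list alone, list adjusted p 0.000164), and 3 of those that fell are CREB-CRTC targets too. Ranks of the statistic ended the NFAT call as well, at an adjusted p of 0.667. RCAN1 at 0.19 ± 0.14 and NR4A1 at -0.38 ± 0.18 did not pass the test in the authors' deposited table, with adjusted p-values of 0.651 and 0.324. Calcineurin-NFAT pathway components fell in 2 of 24 (list adjusted p 0.117), among them RCAN3 at -0.24 ± 0.08 in the authors' deposited table, with an adjusted p of 0.0494, and at -0.20 with an adjusted p of 0.175 once the GC and length trend was removed.

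Among cell type lists, beta cell genes fell in 8 of 29 and rose in 1 in the authors' deposited table (9 and 1 adjusted over the list alone, list adjusted p 5.72e-14), with RFX6 at -0.51 ± 0.06 and PAX6 at -0.42 ± 0.07. Alpha cell genes fell in 2 of 16 and rose in 1 (4 and 1 adjusted over the list alone, list adjusted p 0.00344), with SLC7A2 at -0.32 ± 0.06 and LOXL4 at 0.33 ± 0.09 in the authors' deposited table, the latter at 0.29 with an adjusted p of 0.0724 once the GC and length trend was removed. INS was at 0.06 ± 0.18 and GCG at -0.20 ± 0.13 in the authors' deposited table, neither past the test. Acinar genes had a median of 0.74 and a list adjusted p of 5.56e-05, and ductal genes a median of 0.40 and a list adjusted p of 2.14e-06, yet none of either list was called in the authors' deposited table (0 and 1 adjusted over the list alone). Ribosomal protein genes had a median of 0.09 and a list adjusted p of 5.38e-10 with none called. All 27 acinar, all 21 ductal and all 44 ribosomal protein genes lay above 0. Members that move together are not independent, and the preset correlation of 0.01 allows for little of this. The p-values of these 3 lists may therefore be too small. Beta cell, alpha cell and endothelial genes had medians of -0.11, -0.14 and -0.13, opposite in sign to the acinar and ductal lists. Whether a different mix of cells between wells lowered them was not tested. Metallothionein genes had 1 called, MT2A at 0.45 ± 0.13 in the authors' deposited table (2 adjusted over the list alone, list adjusted p 7.60e-05), which was at 0.40 with an adjusted p of 0.0588 once the GC and length trend was removed. Heat shock genes fell in 2 of 15, with HSPA1B at -0.34 ± 0.09 in the authors' deposited table (3 adjusted over the list alone, list adjusted p 0.000966). Endothelial and interferon-stimulated genes had no called member, and their list adjusted p-values of 0.0156 and 0.0146 became 0.0649 and 0.102 with a preset correlation of 0.05, the endothelial one also 0.107 with an overall mean of at least 100. The other lists had adjusted p-values from 0.117 to 0.98, with at most 2 called members each. Among these, mitochondrially encoded genes tested lower with ranks (0.0146) and with the GC and length trend removed (0.00138), and stellate genes lower with that trend removed (0.045). Glucose-regulated genes tested higher without shared genes (adjusted p 0.0101).

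Genes lower with FK506 had a median GC content of 41.4% against 46.5% in all genes with an adjusted p, and across 12009 genes, which are not independent replicates, Spearman's rho of GC content and log2 fold change was 0.34, with a median GC content of 55.0% in genes higher with FK506. With the trend on GC content and transcript length removed, 217 genes passed, 180 of them lower and 37 higher. A t reference of 2 degrees of freedom was too strict to decide, and with it 0 passed, against 125 at an unadjusted p under 0.05.

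**Figure D2:**
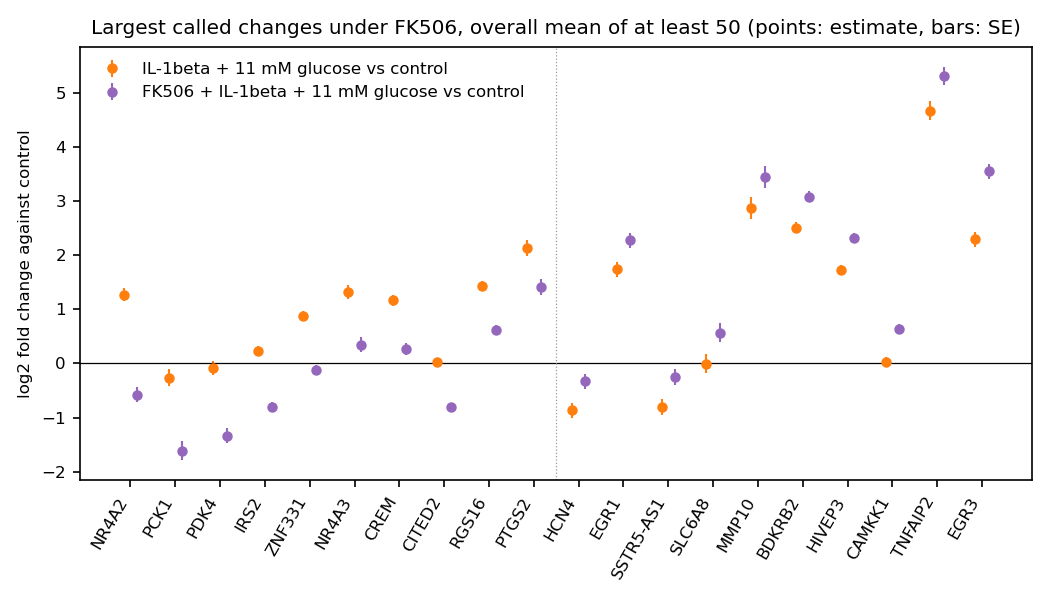
Log2 fold change against control (y axis) without FK506 (orange) and with it (purple) for the 10 largest falls (left) and the 10 largest rises (right) under FK506 among called genes with a symbol and an overall mean of at least 50; points are the authors' estimates and bars the SE. NR4A2 went from 1.27 above control to -0.58, and EGR3 from 2.29 to 3.55.

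Inflammatory genes were also far above control with FK506. In the authors' deposited table, 4126 genes differed between FK506 plus IL-1beta and control, 2423 higher and 1703 lower. CXCL3 stood at 8.02 ± 0.40, CCL20 at 7.90 ± 0.41, SELE at 7.05 ± 0.19, NFKBIA at 4.68 ± 0.14, CXCL8 at 6.28 ± 0.22 and IL6 at 3.22 ± 0.27 in the authors' deposited table. NF-kB pathway genes rose in 24 of 25 (25 adjusted over the list alone, list adjusted p 2.37e-159) and chemokines in 15 of 18 (15 adjusted over the list alone, list adjusted p 2.86e-48). Over the 3651 genes called without FK506, the slope of the response with FK506 on that without was 0.998, being 1.011 for raised and 0.888 for lowered genes. The slope was 1.025 over NF-kB pathway genes, 1.046 over reported NFAT target genes and 0.463 over CREB-CRTC target genes, and lists with at least 5 called members ranged from 0.463 to 1.207. A slope of this kind is set mostly by the largest changes. In the NFAT list the largest rise was that of CSF2, at 9.71 without FK506 and 10.6 with it. CSF2 was listed at 0 in control, so neither fold has a firm size, and the slope of the list rests largely on them. All 19 measured members are in another list too. The slope over the NFAT list does not show that each NFAT target kept its response, as 4 of the 19 fell with FK506 and 1 rose. With no response left under FK506, the shared control libraries alone would give a mean slope of 0.07 over all genes called, in 100 simulations. The genes were chosen by their response without FK506, so a slope somewhat under 1 can arise even with the whole response kept. That case was not simulated, so slopes such as 0.888 do not show a partial reversal. These slopes were described and not tested.

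Some genes of islet identity and metabolism lay below control. Beta cell genes fell in 14 of 29 and rose in 2 (16 and 2 adjusted over the list alone, list adjusted p 3.30e-11), with NKX6-1 at -1.41 ± 0.08 and ISL1 at -1.12 ± 0.08 in the authors' deposited table. Alpha cell genes fell in 10 of 16 (11 adjusted over the list alone, list adjusted p 1.04e-07), with IRX2 at -1.27 ± 0.14 in the authors' deposited table. PCK1 at -1.61 ± 0.18, IRS2 at -0.81 ± 0.10, the potassium channel gene KCNJ8 at -1.94 ± 0.19 and CYSLTR2 at -1.81 ± 0.37 also fell in the authors' deposited table. Ribosomal protein genes rose in 37 of 44 (43 adjusted over the list alone, list adjusted p 1.80e-05), with RPL10 at 0.35 ± 0.08 in the authors' deposited table. Metallothionein genes rose in 5 of 7 (5 adjusted over the list alone, list adjusted p 0.0398), with MT2A at 1.29 ± 0.13 in the authors' deposited table. Both families have near-identical copies or pseudogenes, so their counts are uncertain. CREB-CRTC target genes rose in 9 and fell in 4 of 21 (10 and 4 adjusted over the list alone, list adjusted p 0.326), and endothelial genes fell in 7 of 15 (7 adjusted over the list alone, list adjusted p 0.00221). Acinar genes had a median of 0.88 with none called (list adjusted p 0.402), and ductal genes rose in 6 of 21 (list adjusted p 0.346). Spearman's rho of GC content and log2 fold change was 0.24 across genes. With ranks the acinar (adjusted p 0.000237), ductal (0.0426) and mitochondrially encoded (0.000272) lists tested higher. The metallothionein call ended with the trend on GC content and length removed, at an adjusted p of 0.0887, with a preset correlation of 0.05, at 0.0753, and with an overall mean of at least 100, at 0.147. A t reference of 2 degrees of freedom was too strict to decide, and with it 0 genes passed, against 1846 at an unadjusted p under 0.05.

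FK506 moved back few of the genes that had changed with IL-1beta and high glucose. Of the 2506 IL-1beta-changed genes tested in both of the authors' deposited tables, 120 (4.8%) moved back, 114 of them raised and then lowered, and 73 moved further. Independent lists would share 50.9 raised-then-lowered genes (114 observed) and 5.3 lowered-then-raised genes (6 observed). For genes moved further they would share 10.4 raised by both (39 observed) and 25.8 lowered by both (34 observed). Lowered-then-raised genes were thus about as many as in independent lists, and the other numbers lay above them. Independent lists treat every gene as equally likely to be called, which the SEs do not bear out, so an excess alone decides nothing. In 100 simulations of unchanged groups with shared IL-1beta libraries 0 genes moved back, which is no reference for genes that IL-1beta did change, since hardly any gene is called in both when nothing changes. Part of the excess in moved-back genes may come from the shared libraries, since groups of 2 could not be divided. The covariance of the 2 log2 fold changes over 12022 genes was 0.0007 against -0.0117 in the simulated groups, a difference of 0.0124. The simulated value follows from the deposited SEs, which come from a fit with further libraries. These SEs need not equal the spread between the wells used here, so the difference decides nothing. Of the 259 genes lower with FK506, 114 had been raised by IL-1beta, 111 had not been called and 34 had been lowered.

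**Figure D3:**
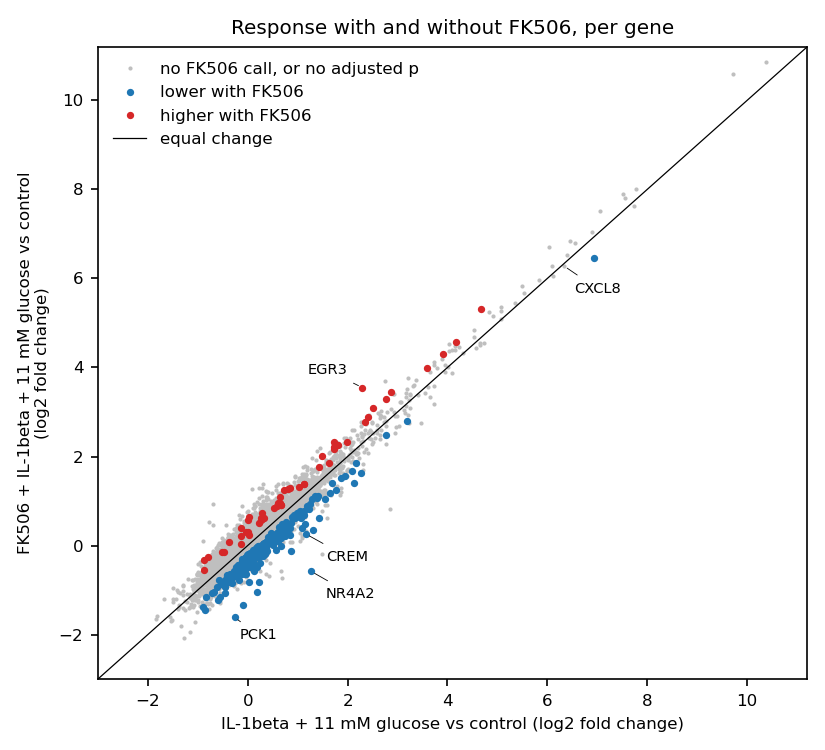
Log2 fold change against control with FK506 (y axis) and without it (x axis) for genes with an overall mean of at least 50; blue and red points were lower and higher with FK506, grey points were not called or had no adjusted p, and the line marks equal change. CXCL8 lies near the line, at 6.33 without and 6.28 with FK506, and NR4A2 lies below it.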

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

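The tests of the CREB-CRTC and NFAT lists without shared genes and without CREM, NPAS4 or EGR3, of chance in the IL-1beta libraries and of the CREB-CRTC genes after the GC trend was removed were chosen after the results were seen, and the share of lowered genes kept without the trend was fixed before.

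A difference between groups marked 4 genes, which lay above control with IL-1beta and below it with FK506 added, with the 2 treated groups differing in the authors' deposited table. They were NR4A2 at -1.85 ± 0.13, DAPK1 at -0.54 ± 0.07, SMOC1 at -0.50 ± 0.09 and ALPK3 at -0.39 ± 0.06 for FK506 plus IL-1beta against IL-1beta in the authors' deposited table. CCDC184 showed the same signs against control, and at -1.42 ± 0.22 it had no adjusted p for that difference in the authors' deposited table.

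The first pattern weighed is the fall of some CREB-CRTC target genes with FK506. With the GC trend removed the list as a whole still tested lower (adjusted p 8.43e-22). The trend removed had an SD of 0.05 on the log2 scale, and NR4A2 went from -1.85 to -1.86. The list test weighs large statistics most, so this removal could hardly end its call. It leaves open a GC effect on the smaller falls. Of the lowered genes 64.9% stayed called, as did 4 of the 6 called list members. PDE10A went from -0.39 to -0.31 (SE 0.10, adjusted p 0.0733) and PDE4D from -0.25 to -0.19 (SE 0.07, adjusted p 0.151). Their calls ended because the folds shrank at the same SE. A check against control cannot decide whether the 2 IL-1beta libraries were high by chance, because without them no value gives the level with IL-1beta. With FK506, 3 of the 6 called members lay below control in the authors' deposited table, which decides nothing either way. Spread between libraries is weighed by the deposited tests, which the 6 called members passed, from NR4A2 (adjusted p 1.72e-40) to PDE4D (adjusted p 0.0158). Those members were picked by the same tests, so this does not speak for the list. Chance lows in the FK506 libraries stay open for the list too. Action of calcineurin through CREB-CRTC may contribute: without genes shared with the NFAT list, the list of 17 tested lower than other genes (p 0.0003445) with 9 members below 0 and a median of -0.08, but this rested on CREM and NPAS4, without which p was 0.596. Loss of NFAT-driven transcription also stays open. The 15 NFAT targets outside the CREB-CRTC list, all of them in some other list, had a median of 0.06 with 7 of them below 0. Their list test, higher than other genes at p 0.0159, rested on EGR3, without which p was 0.977. The bound first set, a median at or above 0, was badly chosen, since such a median decides nothing.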

How the results depend on the processing

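Removal of the GC and length trend and lists without shared genes were chosen after seeing the data. No paired analysis was possible because the deposited tables hold no values of single libraries, and for the same reason leaving out replicates, edgeR against DESeq2 refits, pseudocounts and fits without a filter on counts were not run. Total counts of changed genes, moved-back genes and lists stayed within 1.5 times the reported ones except where stated, and the cause was not tested unless given. With a change of at least 2-fold also required, by construction fewer genes passed: 954 for IL-1beta against control, 6 for FK506 plus IL-1beta against IL-1beta and 1052 for FK506 plus IL-1beta against control. At an adjusted p under 0.01, 199 genes passed for FK506 plus IL-1beta against IL-1beta, 30 higher and 169 lower, while 796 were lower for IL-1beta against control and 1101 for FK506 plus IL-1beta against control. At an adjusted p under 0.1, 87 were higher for FK506 plus IL-1beta against IL-1beta. With a t reference of 2 degrees of freedom 0 passed in each comparison, with unadjusted p under 0.05 in 1650, 125 and 1846 genes. That reference ignores the information on spread that DESeq2 shares across genes, and 2 is fewer than the authors' fit of all groups leaves. Its lowest adjusted p was 0.453 for IL-1beta against control and 0.446 for FK506 plus IL-1beta against control. Even the largest statistics could not pass it, so its 0 calls decide nothing. The number moved back by FK506 ranged from 80 to 163, and was 97 with the GC and length trend removed. The slope of the response kept was 1.01 at an overall mean of at least 100, 1.005 for changes of at least 2-fold, 0.979 with weights and 0.993 without the GC and length trend.

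Lists that passed numbered 12 to 16, 11 to 15 and 13 to 17 over the settings, in the order above. Some lists past no threshold turned direction, the cause not tested. The median and the test differed in sign for unfolded protein and cell cycle genes in FK506 plus IL-1beta against IL-1beta and for macrophage and glucose-regulated genes in FK506 plus IL-1beta against control, none past the threshold. For IL-1beta against control with ranks these were acinar (adjusted p 0.457), stellate (0.512), macrophage and lymphocyte and mast cell genes (0.797 each), with an overall mean of at least 100 macrophage genes (0.77), and without the GC trend glucose-regulated and hypoxia genes (0.969 each). For FK506 plus IL-1beta against IL-1beta these were unfolded protein genes with ranks (0.683) and macrophage genes at a mean of at least 100 (0.152) and without the GC trend (0.899). For FK506 plus IL-1beta against control these were macrophage genes with ranks (0.734), glucose-regulated genes at a mean of at least 100 (0.924) and without shared genes (0.799), and mitochondrially encoded genes without the GC trend (0.962). Without the GC trend the log2 fold change turned to 0.0839 for CXCL8 and -0.0392 for INS in FK506 plus IL-1beta against IL-1beta, neither called before or after, and to -0.0215 for MT-ND3 against control, which lost its call. Depth limits the genes of low overall mean, where the median SE was 0.50.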

Other observations

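The tests of acinar genes and the comparison of transcription factor with other beta cell genes were chosen after the results were seen, and the GC test of endocrine genes was fixed before.

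Several further genes moved with FK506 but lay below the overall mean at which the authors' deposited table gives an adjusted p. With adjustment over all genes, 24 such genes passed, 19 lower and 5 higher, while 57 genes called in the authors' deposited table no longer passed. The activity-dependent transcription factor gene NPAS4 was at -1.67 ± 0.22 and the growth factor gene AREG at -2.03 ± 0.31, while the activity-regulated gene ARC was at 1.40 ± 0.38 and the metallothionein gene MT1G at 1.20 ± 0.31 in the authors' deposited table, all chosen after their values were seen. The mitochondrial ribosomal RNA genes MT-RNR1 at 4.74 ± 2.18 and MT-RNR2 at 4.65 ± 2.02 had SEs near 2 in IL-1beta against control in the authors' deposited table and were not called.

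The second pattern weighed is the fall of islet transcription factor genes with IL-1beta and high glucose. The 10 transcription factor genes of the beta cell list had a median of -0.79 and 8 of them fell, a split made after these falls were seen, so the difference is not tested. A loss of endocrine cells as the whole cause would lower the 19 others by about as much, and their median of -0.04, with 7 lower and 3 higher, lay above -0.79 by more than their SD of 0.57 across genes. With the GC and length trend removed, 96.4% of the 28 endocrine genes called lower stayed called. Lower transcription of these genes, or faster loss of short-lived messages, may account for the pattern, and neither was tested.

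The third pattern weighed is the higher level of acinar genes with FK506. All 23 acinar genes with an overall mean of at least 100 lay above 0, with a median of 0.74, an SD of 0.22 across genes and a median SE of 0.64, against a median SE of 0.12 for all genes of that mean. Unequal carry-over of acinar cells between wells is a candidate explanation that these values meet, and PRSS1 at 0.61 ± 0.64 and CPA1 at 0.74 ± 0.63 in the authors' deposited table are examples chosen after their values were seen. The 16 ductal genes of that mean also all lay above 0, with a median of 0.42, an SD of 0.23 and a median SE of 0.28. The shift was therefore not limited to acinar genes. A response of acinar genes to FK506 cannot be told apart from unequal carry-over. None of them passed the adjusted test, and a change within the spread between the libraries of the fit does not show.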
